A study of Solanum lycopersicum with 4 samples.

How the data were processed

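The data were 4 small RNA libraries from leaves of the tomato rdr6 mutant, made without TAP treatment, 2 with HD adapters and 2 with standard Illumina adapters. Groups and replicate numbers were taken from the sample labels. The adapter is the one in the adapter field, while the protocol text names standard adapters for all 4 libraries, those marked HD included, and this conflict was not resolved. Per the labels, leaf RNA was used to build Illumina-compatible small RNA libraries. The deposited values are read counts: each file gives every distinct read sequence joined as text with its whole-number count, and the authors had already removed 3′ adapters and collapsed identical reads, as the sequences themselves show. The counts were not normalised, and no genome match is recorded. The adapter trimming tool, its settings, any length limit and any treatment of the degenerate bases of the HD adapters are not given in the sources used here. The HD files held sequences of 17 to 33 nt and the standard files of 17 to 41 nt, a difference of 8 nt in the longest length. No sequence occurred more than once in a file.

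Sequences of 18 to 28 nt were analysed, and library size was the number of such reads. CPM values are counts scaled to it alone, while fold changes of sequences come from the test with its further scaling, given below. Total depth was 3934978 to 6362728 reads per library. A sequence with 0 reads has a floor of 3 counts, 0.495 to 0.788 CPM depending on the library. Without molecular identifiers, reads are not independent molecules, so such floors cover counting error only.

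The planned test for counts was a quasi-likelihood count model. In place of it, limma 3.58.1 (R 4.3.3) was used on log2 CPM with voom precision weights and a prior count of 0.5. The counts split from the deposited text would have allowed a count model, but models planned as main test and as alternative were not run. Library sizes were scaled by the trimmed mean of M values, with 0.3 of log ratios and 0.05 of mean abundances trimmed. A sequence was tested if at least 2 libraries reached the CPM that 10 reads have in the median library (2.12 CPM) and if it had at least 15 reads in total. When a library was left out, any remaining library reaching that CPM was enough. No replicate block was used, since nothing in the labels pairs the libraries. P-values were adjusted by Benjamini-Hochberg over all tested sequences, with a threshold of 0.05. Reads per length, per first base and length, and per first or last 4 bases were compared by limma on log2(CPM + 1), scaled by library size only, with adjustment within each table. The sequences of the standard 5′ and 3′ adapters, used to find adapter bases and complementary ends, came from general knowledge and not from the labels. Lists of sequences were tested with limma's camera at a preset correlation of 0.01 and again with an estimated one. Complexity was compared after thinning each library without replacement to the reads of the smallest one, with an exact two-sided permutation test. Correlations used log2(CPM + 1).

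The lists of mature sequences were fixed before the data were examined: miRNAs of development, of nutrient and stress responses, of the silencing pathway, of the miR482 superfamily and Solanaceae, passenger strands, tasiRNAs, 5′ fragments of tRNA, and miRNAs of other organisms as a control. Sequences were matched exactly. End variants were also summed as all sequences of 18 to 26 nt that hold the mature sequence without its 2 first and 3 last bases. By a rule fixed at the same time, the named miRNAs were up to 10 with the largest log2 fold change in each direction, among those past the threshold with non-overlapping library values. The named sequences outside the lists were up to 5 in each direction by the same rule with a mean of at least 100 CPM. The most abundant sequence and miRNA of each group, the tasiRNAs and the classes of 21 to 24 nt were always named. The named tetramers were up to 5 in each direction at each end with a mean share of at least 0.1%. Other members of the lists are named to describe their list and were chosen after their values were seen. Sequences were not matched to a genome, so positions and annotation classes are not analysed here, and miRNAs of identical sequence from different loci are counted together.

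The test was tried on simulated counts for the 39431 tested sequences with a dispersion of 0.02. It recovered 20% of 50 sequences changed 2-fold, 62% of 50 changed 4-fold, 84% of 50 changed 8-fold and 98% of 50 changed 16-fold, and called 3 of 39231 unchanged sequences. The test of tetramers, simulated with a smaller dispersion, recovered 100% of 20 changed 2-fold and called 3 of 236 unchanged ones. Its rates therefore cannot be set beside those of the sequences. In both simulations most sequences or tetramers were unchanged and as many rose as fell, whereas 73.8% of the tested sequences were called in the data. The rates therefore do not describe recovery or false calls where most sequences differ, and the scaling was not tried in that setting. Alternatives covered the scaling, the filter, voom weights, the replicate block, each replicate left out, the length range, distinct sequences in place of reads, sequences with 1 read, the most abundant sequences, sequences with adapter bases, end variants, the thinning depth and the pseudocount. Sequences with adapter bases were left out only in the fits of sequences, not for size classes, tetramers or complexity. Predicted folding energies came from RNAfold (ViennaRNA 2.7.2). Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.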

Results

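Small RNAs were sequenced from leaves of tomato (Solanum lycopersicum) carrying a mutation in RDR6, an RNA-dependent RNA polymerase that makes the double-stranded precursors of trans-acting siRNAs. The libraries differed in the adapters ligated to the RNA. By general knowledge of the methods, not by the labels, standard Illumina adapters have a fixed sequence at the ligated ends, and HD was read as high-definition adapters, which carry degenerate bases there. The RNA was not treated with tobacco acid pyrophosphatase (TAP), so small RNAs with capped or triphosphorylated 5′ ends were not made ligatable before the libraries were built. The comparison addressed how far the small RNA profile of the same kind of tissue depended on the adapter. There were 4 libraries, 2 with each adapter, all from the mutant, so the effect of the mutation itself was not analysed here. The HD libraries held 6362728 and 3934978 reads, and the standard libraries 4305771 and 6026413 reads. Reads of 18 to 28 nt, used below unless stated, numbered 6060452 and 3805853 with HD adapters and 4023215 and 5414816 with standard adapters. Between 78.8% and 80.7% of the distinct sequences of any length in each library had 1 read. Of 6182994 distinct sequences of 18 to 28 nt, 124310 were read in all 4 libraries. Libraries of the same adapter were not copies of each other, with a chi-square per degree of freedom of 3.04 for HD and 6.97 for standard against counting noise, which library preparation alone can exceed. The labels do not say whether they came from separate plants, so p-values measure the spread between these libraries, which may be technical.

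Many listed miRNAs, though not all, differed in abundance between adapters. miR482a targets mRNAs of NLR disease resistance genes. It had 4287 ± 528 CPM (counts scaled to library size) with HD adapters and 183 ± 70.4 CPM with standard adapters (SD, n = 2). By the limma fit it was 28.4-fold higher with HD adapters (log2 fold change 4.83, and 4.22 without standard replicate 1). Folds of sequences below are from that fit and its further scaling unless stated, so they differ from ratios of the printed CPM. Bounds against a floor are ratios of CPM. miR166, which targets mRNAs of HD-ZIP III transcription factors of leaf polarity, lay on the other side, with 342 ± 1.22 CPM with HD adapters and 7511 ± 759 CPM with standard adapters, 18.4-fold lower with HD (log2 fold change −4.20, SE 0.17, limma adjusted p = 4.68e-06). The listed miRNA with the highest mean was miR162, which targets a Dicer-like mRNA, with HD adapters (7835 ± 161 CPM against 2378 ± 81.4 CPM) and miR166 with standard adapters. In standard replicate 2, miR396a (8122 CPM) exceeded miR166 (8048 CPM). Of 45 listed miRNAs and passenger strands, 35 had enough reads to be tested. With HD adapters 20 were higher, 6 were lower and 9 did not pass the test, and 26 were called adjusted over the list alone.

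Among 16 miRNAs of developmental regulation, 10 were higher and 2 lower with HD adapters. miR171b, a regulator of GRAS family mRNAs, was 39.1-fold higher (log2 fold change 5.29, SE 0.53, adjusted p = 8.01e-05), at 41.7 ± 5.45 CPM against 1.36 ± 0.88 CPM. The other listed miR171, miR171a, was 2.09-fold higher. The auxin pathway regulators miR160, miR393 and miR167 were 27.5-fold, 18.7-fold and 8.22-fold higher. miR172, which targets AP2-like mRNAs, was 12.1-fold higher, at 12.1 ± 0.39 CPM against 1.36 ± 1.22 CPM, and miR396b, a regulator of growth-regulating factors, was 4.53-fold higher. Besides miR166, miR156a, which targets SPL mRNAs of the juvenile to adult transition, was lower, at 1293 ± 44.4 CPM against 5616 ± 72.3 CPM (3.63-fold). miR159, miR319, miR394 and miR396a did not pass the test, with log2 fold changes of −0.19, −0.02, −0.07 and −0.25. The log2 fold change of miR172 was 2.45 without standard replicate 1 and 4.43 without standard replicate 2, against 3.60, and that of miR171b was 4.44 without standard replicate 2. Few reads with standard adapters lay behind these folds: 8 and 4 for miR171b, 2 and 12 for miR172, and 7 and 9 for miR160.

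The 10 miRNAs of the miR482 superfamily and others of Solanaceae went both ways, with 5 higher, 3 lower and 2 not passing. Beside miR482a, miR5300 was 5.14-fold higher with HD adapters. miR6027, miR6024 and miR6026 were 2.78-fold, 2.60-fold and 1.72-fold lower. The call of miR6026 was lost without HD replicate 1 (adjusted p = 0.066). Of 4 tested miRNAs that target silencing components, miR162 (3.96-fold) and miR403, a regulator of an ARGONAUTE mRNA, were higher, and miR168, which targets AGO1, was 1.60-fold lower. That call was lost without HD replicate 2 (adjusted p = 0.157). Of 9 nutrient and stress miRNAs only miR398, which targets copper superoxide dismutase mRNAs, passed the filter, at 21.6 ± 3.35 CPM against 5.07 ± 0.14 CPM. Of 4 tested passenger strands, miR390* was 115-fold higher with HD adapters, at 39.7 ± 2.23 CPM against 0.31 ± 0.085 CPM. The value with standard adapters rested on 1 and 2 reads, below a floor of 3 counts, so the size of that fold is uncertain. miR396* was also higher, and miR166* and miR168* did not pass the test. Both tested 5′ fragments of tRNA were lower as exact sequences, that of tRNA-Ala with 36.5 ± 1.18 CPM against 66.6 ± 8.05 CPM. That of tRNA-Gly-GCC rested on 7 and 2 reads with HD adapters and 9 and 17 with standard adapters. The trans-acting siRNAs that target auxin response factors, products of the RDR6 pathway, were at the limit of detection: tasiR-ARF-D7 had 0 and 1 reads with HD adapters and 4 and 0 with standard adapters, and tasiR-ARF-D8 had 0 in all 4 libraries. None of the 10 miRNAs of other organisms had a read, which allows up to 0.495 to 0.788 CPM per library by a floor of 3 counts.

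As sets, none of 5 tested lists stood apart from the other sequences by limma's camera test with a preset correlation. The adjusted p was 0.573 for the developmental list, 0.918 for the miR482 and Solanaceae list, 0.824 for silencing and passenger strands and 0.573 for tRNA fragments. With an estimated correlation it was 0.928 for each of the 5, and 0 lists had an unadjusted p below 0.05 in either form. The miR482 and Solanaceae list had a median log2 fold change of 0.07 and a test direction below 0. The listed miRNAs together made up 2.99% ± 0.063 of reads with HD adapters and 3.49% ± 0.19 with standard adapters. With library size as the only scaling, the split of the miRNA calls was 17 higher and 11 lower, against 20 and 6, since that scaling moved the median log2 fold change of the sequences tested from 0.38 to 0.11. Without standard replicate 1, 13 miRNAs were lower in place of 6.

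The size of some of these differences belonged to the exact mature sequence and not to the whole miRNA. Summed with its end variants, miR390* had 163 ± 3.04 CPM with HD adapters and 56.2 ± 5.27 CPM with standard adapters, a log2 fold change of 1.81 against 6.85 for the exact sequence. miR393 fell in the same way from 4.22 to 1.20, miR160 from 4.78 to 3.16, miR171b from 5.29 to 3.99 and miR398 from 2.33 to 1.17. Of the same nutrient and stress list, miR408 (−1.63, adjusted p = 0.00215) and miR169 (−0.97, adjusted p = 0.0042) passed as sums only and were lower with HD adapters. miR168 went from −0.68 to −1.36. miR396a and miR396b, whose variants are summed together, did not pass (0.30, adjusted p = 0.156). miR482a (4.83) and miR166 (−4.38) kept their differences, and miR319 was higher as a sum (0.98) with no difference for the exact sequence (−0.02). As sums, 20 were higher and 8 lower with HD adapters. The tRNA-Ala fragment was further apart as a sum (−2.29 against −0.60), and the tRNA-Gly-GCC fragment did not pass, at 45.9 ± 4.22 CPM with HD adapters and 39.9 ± 12.8 CPM with standard adapters (0.48, adjusted p = 0.161).

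**Figure D1:**
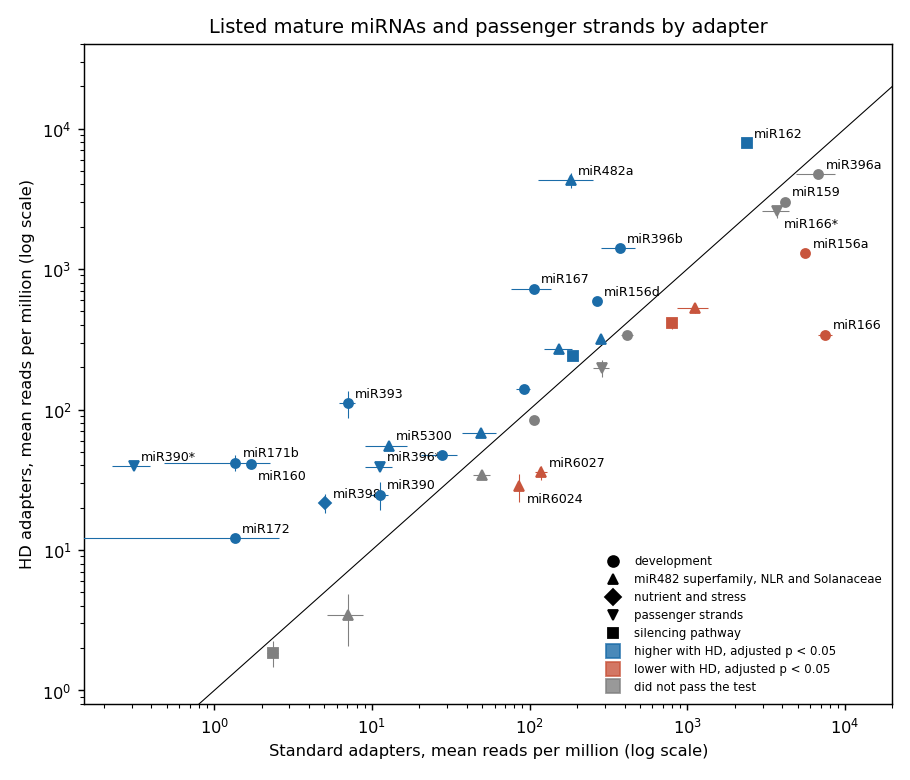
Mean CPM of the 35 tested miRNAs and passenger strands with standard adapters (x axis, log scale) and HD adapters (y axis, log scale), with symbols for the lists, bars for the SD of 2 libraries, colours for the limma call and a line at equal values. miR482a at 4287 against 183 CPM lies far above the line and miR166 at 342 against 7511 CPM far below it.

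The 24-nt small RNAs, the size of siRNAs that guide DNA methylation, made up 43.8% ± 1.51 of reads with HD adapters and 33.3% ± 2.85 with standard adapters (SD, n = 2). The 21-nt class, which holds most miRNAs, made up 9.07% ± 0.38 and 12.2% ± 0.17. There were thus 4.84 ± 0.37 reads of 24 nt per 21-nt read with HD adapters and 2.74 ± 0.27 with standard adapters. The 23-nt class was also larger with HD adapters, at 17.1% ± 0.26 against 13.7% ± 0.18, and the 26-nt class was smaller, at 1.17% ± 0.15 against 2.45% ± 0.038. By limma on log2 shares, the differences were 0.40 (SE 0.11) for 24 nt, 0.33 (SE 0.085) for 23 nt and −0.43 (SE 0.089) for 21 nt, each with an adjusted p of 0.0278. The 18, 20, 25, 26, 27 and 28 nt classes were smaller with HD adapters, and 19 nt did not pass (adjusted p = 0.0525).

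The 22-nt class held 15.3% ± 0.75 and 17.2% ± 1.13 of reads, and its difference of −0.18 did not pass (adjusted p = 0.160). It hung on the most abundant sequence of every library, the 22-nt AGTTACTAATTCATGATCTGGC, which took 3.09% ± 0.23 of reads with HD adapters and 8.34% ± 1.08 with standard adapters. Without it, the 22-nt class was larger with HD adapters, by 0.37 (adjusted p = 0.0226). The calls of 21, 23 and 24 nt kept their direction but missed the threshold when any of the 4 libraries was left out, with adjusted p from 0.0774 to 0.277. They also missed it without the 100 most abundant sequences of each library, where the 21-nt difference was −0.38, close to −0.43, and the 23-nt and 24-nt differences were 0.23 each. With distinct sequences in place of reads the 24-nt class missed it (0.22, adjusted p = 0.0596), as did the 23-nt class without sequences of 1 read (0.30, adjusted p = 0.0519).

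**Figure D2:**
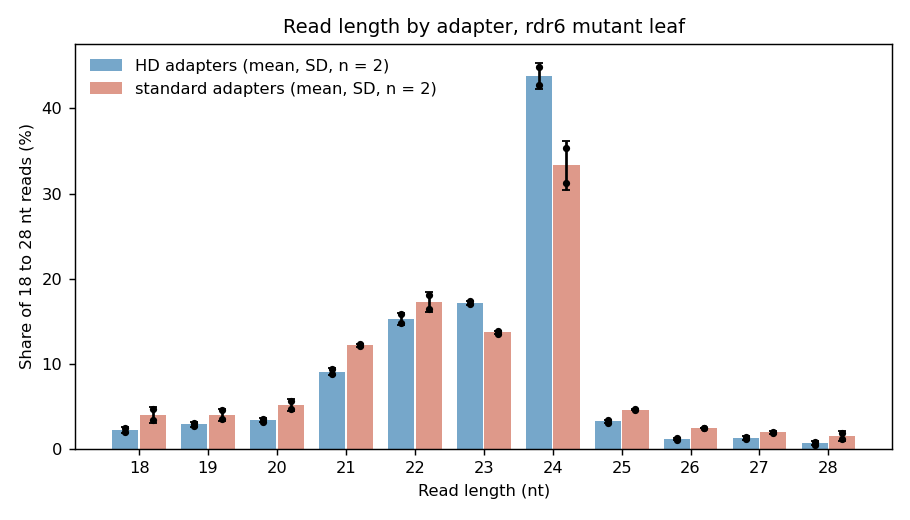
Share of 18 to 28 nt reads (y axis, percent) at each read length (x axis, nt), with bars for the means of 2 libraries with the SD and points for the libraries. The 24-nt class reaches 43.8% with HD adapters and 33.3% with standard adapters, and the 21-nt class 9.07% and 12.2%.

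The first base of a small RNA follows its sorting into ARGONAUTE proteins and also lies at the 5′ ligation junction. With HD adapters, 24-nt reads starting with A took 28.1% ± 1.29 of reads against 20.5% ± 1.69 (log2 difference 0.46), and those starting with G took more reads as well (4.25% ± 0.35 with standard adapters, log2 difference 0.72). Within the 24-nt reads A was the first base of 64.1% with HD adapters and 61.6% with standard adapters, so the A difference was mostly that of the 24-nt class. Within the 23-nt reads the shares of A were 40.5% and 29.7%. Reads of 23 nt starting with A (0.77) or G (0.51) and of 22 nt starting with G (0.89) were also more frequent. Reads of 21 nt starting with T, the usual form of miRNAs, fell from 6.16% ± 0.31 with standard adapters to 3.93% ± 0.074 with HD adapters (−0.65, adjusted p = 0.00712). Abundant members of this class went both ways. TCTCGGACCAGGCTTCATTCC took 0.0123% of reads with HD adapters and 1.17% with standard adapters, and miR166 and miR156a were also lower. miR162 (7835 ± 161 CPM against 2378 ± 81.4 CPM), miR167 and miR396b were higher. Which members set the class difference was therefore not shown. Without the 100 most abundant sequences of each library, the 21-nt class over all first bases was at −0.38, against −0.43 with them. Reads of 22 nt starting with A were lower, at 6.58% ± 0.31 against 10.8% ± 1.10 (−0.71), but AGTTACTAATTCATGATCTGGC alone took 3.09% and 8.34% of all reads, a wider gap than that of the class. In all, 5 of the 44 classes of first base and length were higher with HD adapters and 22 were lower by limma. The number higher was 2 and the number lower 12 without HD replicate 1, and 2 and 8 without HD replicate 2. Without standard replicate 1 or 2, 3 classes were higher.

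Counted by reads, the bases next to both ligation junctions differed between adapters by several fold, for some tetramers mainly through abundant sequences. Reads ending in GCCT were 13.9-fold less frequent with HD adapters, at 0.114% ± 0.0028 against 1.58% ± 0.063 (SD, n = 2). Reads ending in CCTA, CCAG, TCCG, CCCG and ACCG were 5.18-fold, 4.90-fold, 4.78-fold, 4.52-fold and 4.28-fold more frequent. Endings in CCCC, GAAC, CAGC and TCGT were 5.23-fold, 3.55-fold, 3.16-fold and 2.71-fold less frequent. At the 5′ end, GGCT, GACT, AGCT, GACA and TACA were 4.09-fold, 3.77-fold, 3.36-fold, 3.23-fold and 3.03-fold more frequent with HD adapters. TCTC, TCGG, GGGG, CAGA and CGCG were 5.94-fold, 5.92-fold, 3.31-fold, 3.02-fold and 2.57-fold less frequent. Among all tetramers, limma called 105 higher and 94 lower with HD adapters at the 5′ end, and 140 higher and 70 lower at the 3′ end. Reads with 12 bases of the 5′ adapter were kept in these counts. They made up 0.959% and 1.64% of reads in the HD libraries and 0.0571% and 0.0618% in the standard libraries. Of the tetramers more frequent with HD adapters, TACA and TCCG also occur in that adapter, and the part of such reads in them was not tested. With each sequence counted once per library, GCCT at the 3′ end kept most of its log2 difference (−3.51 against −3.79), and TCCG (1.67 against 2.26) and GACT at the 5′ end (1.46 against 1.92) kept more than they lost. CCTA fell from 2.37 to 0.57, CCCC from −2.39 to −0.62, GAAC from −1.83 to −0.32, CAGC from −1.66 to −0.46 and TCGT from −1.44 to −0.70. At the 5′ end AGCT fell from 1.75 to 0.35, TACA from 1.60 to 0.35, GGCT from 2.03 to 0.98, CAGA from −1.60 to −0.30 and TCGG from −2.57 to −0.87. TCTC showed no difference (−0.03, limma adjusted p = 0.453). The tetramers singled out here were chosen after their values were seen. Without the 100 most abundant sequences of each library, the split at the 5′ end was 70 higher and 137 lower.

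**Figure D3:**
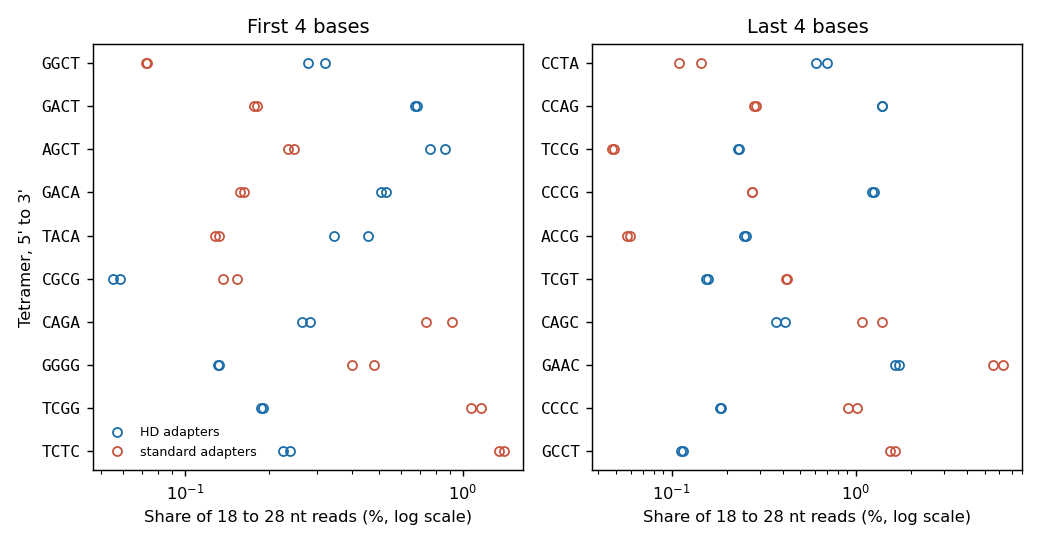
Share of 18 to 28 nt reads (x axis, percent, log scale) with the named first 4 bases (left) or last 4 bases (right), written on the y axis, with a circle for each of 2 libraries per adapter. For every tetramer shown the libraries of the adapters stand apart, as for GCCT at the 3′ end at 0.114% with HD adapters and 1.58% with standard adapters.

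Reads were spread over more distinct read sequences with HD adapters. They were not matched to a genome, and the treatment of the degenerate bases is not stated. Exact listed miRNAs took 2.99% ± 0.063 of reads with HD adapters and 3.49% ± 0.19 with standard adapters. The largest length class was 24 nt with both (43.8% and 33.3%). These values argue against degenerate bases left on most HD reads but cannot exclude them on a minor part. More distinct sequences thus need not be more small RNAs. At an equal depth of 3805853 reads, the HD libraries held 1797542 and 1713343 distinct sequences and the standard libraries 1338481 and 1418077, a ratio of 1.27 ± 0.068. The 10 most abundant sequences took 7.24% ± 0.47 of reads with HD adapters and 15.6% ± 1.32 with standard adapters, and the 100 most abundant took 14.4% ± 0.59 and 25.8% ± 1.66. For each of these measures both HD libraries lay on the same side of both standard libraries. The exact permutation test gave a two-sided p of 0.33 each time, the smallest that 2 against 2 libraries allow.

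Single read sequences differed between adapters far more than between libraries of the same adapter. Related forms that differ by 4 nt at the 3′ end stood out, the 24-nt AGCCAATGATGATTTTTATATAAA with 19977 and 8677 reads with HD adapters and 0 with standard adapters, and its 28-nt form AGCCAATGATGATTTTTATATAAATATT with 4924 and 34879 reads with standard adapters and 0 with HD adapters. Against a floor of 3 counts per library, the first was at least 4290-fold higher and the second at least 5973-fold lower with HD adapters. The second bound was 1907-fold without standard replicate 2 and 10039-fold without standard replicate 1. Both bounds belong to the exact 3′ ends. The 24-nt form had 2788 ± 719 CPM with HD adapters, and the 28-nt form 3833 ± 3689 CPM with standard adapters. If the forms are the same RNA read to different 3′ ends, these are its levels with each adapter, and they differ far less. The 27-nt CTGACTGGCCAGCTCACGGCTGTCCAG, with 20191 and 13397 reads with HD adapters and 0 with standard adapters, was at least 5272-fold higher, and its 26-nt form CTGACTGGCCAGCTCACGGCTGTCCA at least 587-fold. GGCTGTAGTTTAGTGGTAAGAATTCCA had 795 ± 155 CPM with HD adapters and 0.40 ± 0.22 CPM with standard adapters, and ACTGATACAAATACGAGGGTCCAC 333 ± 3.94 CPM and 0.18 ± 0.26 CPM. On the other side, TCTCGGACCAGGCTTCATTCC, a miR166 form that starts 2 nt upstream of the listed sequence, had 123 ± 18.3 CPM with HD adapters and 11732 ± 376 CPM with standard adapters, 80.9-fold lower. The overlapping CGCGCTCCGGACGCTGGCCT and GCGCGCTCCGGACGCTGGCCT were 91.6-fold and 68.9-fold lower, and ATGATCGGGATAGCGAACCAAAAGCTA, with 0 reads with HD adapters, at least 411-fold lower.

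Of 39431 sequences tested by limma voom, 16758 were higher and 12361 lower with HD adapters, together 73.8%. At least 4-fold differences were found in 22026 sequences, 13697 of them higher, and at least 16-fold differences in 9967. Of 20585 tested sequences of 24 nt, 9693 were higher and 5167 lower, while of 2381 of 21 nt, 812 were higher and 986 lower and of 655 of 26 nt, 82 were higher and 404 lower. Of the tested sequences, 933 held 12 bases of the standard 5′ adapter, and without these 15352 were higher and 12927 lower. The share called depended on the filter. Without a filter on reads beyond 10 in total the counts were 43854 and 26428, together 47.0% of 149489. Over sequences with at least 10 CPM in 2 libraries they were 3124 and 2922, together 86.2% of 7010.

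Libraries of the same adapter ranked the tested sequences alike, with a Spearman rho across sequences of 0.917 for HD and 0.935 for standard adapters. Between adapters rho lay from −0.163 to −0.138. Sequences are not independent replicates, so no p is given. These values rest on the filter, which keeps sequences that are abundant with either adapter. Over the sequences with reads in every library, a set chosen after seeing the data, mean rho was 0.737 within and 0.404 between adapters. Over the 35 tested miRNAs, rho was 0.995 and 0.994 within adapters and 0.829 to 0.859 between them.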

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

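The tests of library depth, of forms shorter by 4 nt, of 5′ adapter fragments and of the 3′ end motif were chosen after the results they bear on were seen. Reads outside 18 to 28 nt were left out of the comparisons, yet every library held them. Reads of 17 nt made up 1.82% of all reads with HD adapters (1.55% and 2.10%) and 3.06% with standard adapters (3.71% and 2.42%). Reads of 29 to 33 nt made up 2.19% with HD adapters (3.20% and 1.18%) and 4.94% with standard adapters (2.71% and 7.17%), so that the libraries of the adapters overlapped. Reads of 34 to 41 nt made up 0.35% with standard adapters (0.139% and 0.562%) and were not in the HD files. The sequence of 29 nt or more with the most reads over the 4 libraries together was the 32-nt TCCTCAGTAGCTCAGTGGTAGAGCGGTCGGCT, with 6621 and 1208 reads with HD adapters and 12476 and 60235 with standard adapters. In both HD libraries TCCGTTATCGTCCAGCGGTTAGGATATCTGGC (10975 and 2080 reads) and ATTCGGTTAGGATCAATCTAAACCAACCC (9216 and 2081) exceeded it.

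The 24-nt class was larger with HD adapters, 43.8% against 33.3% of reads. Depth is argued against, since the shallowest library, an HD library with 3805853 reads, exceeded the deepest standard library by 0.28 on the log2 scale, more than the 0.17 between libraries of the same adapter. The first 2 and last 2 bases alone do not account for it either. Within strata in which these are equal the mean log2 difference was 0.41, with 0.53 and 0.29 in the library pairs, which were matched by replicate number only. Longer stretches at the read ends were not tested and stay open. A part carried by abundant sequences stays open: without the 100 most abundant sequences of each library the difference was 0.23 (SE 0.104, adjusted p = 0.0892) against 0.40 (SE 0.107), so the call ended because the difference became smaller at a similar SE. The adapter is the only difference the labels give, so no biological explanation was tested.

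Most tested sequences differed between adapters, in both directions. The 4 bases at each end predicted the log2 fold change with an R2 in held-out sequences of 0.135, against 0.033 for 8 central bases, and the first 4 and last 4 bases alone gave 0.059 and 0.079. Bases next to the ligation junctions are therefore a candidate explanation for a part of the differences, and most of the variation was left unpredicted. Sequences were held out singly, so reads that share an end fell into both the fitted and the held-out part. This may have raised the R2 of the end bases more than that of the central ones. The 933 sequences with 5′ adapter bases were kept in. Across sequences, log2 fold change had a Spearman correlation of −0.128 with GC content and of 0.123 with predicted folding energy, between the bounds set for either reading, so both stay open. No biological explanation was tested, since the design gives none.

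Sequences with at least 20 reads in both libraries of an adapter and 0 with the other numbered 314 with standard and 1491 with HD adapters. Of the 314, 17, the named 28-nt form among them, had a form 4 nt shorter at the 3′ end that was read only with HD adapters. With at least 40 reads of that shorter form in place of 20, there were 11. No other shortening of 1 to 8 nt gave more than 1. The 17 held 57.9% of the reads of the 314. Of 392 distinct sequences that extend these 3′ ends, 75.5% go on with TGG, the start of the 3′ adapter, against 2.24% for abundant sequences of all libraries, with 36.6% without the 3′ end that has the most extensions and 91.7% for the 11, so longer RNAs that were trimmed at an adapter-like stretch, with 4 more bases removed in the HD files, may explain a part of these 17, since 4 of their 7 distinct 3′ ends had a majority of such extensions, and leave the other 297 open. Of the 1491, 35.7% held 12 bases of the 5′ adapter, short of a majority, and these could be adapter fragments. Of the 959 others, 23.7% had ATTCC or TTCCA, complementary to the start of the 3′ adapter, in their last 8 bases, against 2.26% of all tested sequences, which is consistent with poor capture of such ends by standard adapters but leaves most of the 959 unexplained and does not hold for every such end, since TCTCGGACCAGGCTTCATTCC and miR166 were far higher with standard adapters.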

How the results depend on the processing

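Limma-trend, the leaving out of adapter-bearing sequences, of the most abundant sequences in the size classes, and the correlation over sequences with reads in every library were chosen after seeing the data. The planned count models, annotation classes and genome-matched alternative were not run. Of the values of single named miRNAs under alternatives, 189 kept direction and side of the threshold and 3 no longer passed. No call for a sequence was reversed under any alternative. Library size as the only scaling gave 15812 sequences higher and 13978 lower. Without the filter 43854 were higher and 26428 lower, 47.0% of those tested. At 10 CPM or more they numbered 3124 and 2922, 86.2% of those tested. The filter thus set both the number tested and the share called. With a library left out, 14382 to 22127 were higher and 10894 to 16661 lower. The lone library is then assumed to vary like the other group. The filter also changed in these fits, since any library reaching the CPM threshold was enough. They tested 43039 to 60926 sequences, against 39431, so their counts do not show the loss of a library alone. The miRNAs higher and lower numbered 17 and 11 with library size only, 19 and 10 without the filter, and 19 to 20 and 5 to 13 with a library left out.

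For the size classes, distinct sequences in place of reads turned 22 nt to 0.24 (adjusted p = 0.0376) and took 24 nt to 0.22 (0.0596). Without the 100 most abundant sequences, 21 nt was at −0.38, 22 nt at 0.22, 23 nt at 0.23 and 24 nt at 0.23, none of them past the threshold. Without the most abundant sequence 22 nt was at 0.37, which shows what set its direction. With a denominator of 20 to 24 nt it was at −0.30 (0.0218). Without sequences of 1 read 23 nt was at 0.30 (0.0519). With a library left out, 21 nt lay from −0.47 to −0.38, 23 nt from 0.31 to 0.34 and 24 nt from 0.31 to 0.48. Fewer libraries leave fewer degrees of freedom in these tests; the cause of the other changes was not tested. The classes of first base and length higher with HD adapters numbered 2 to 3 and those lower 8 to 21 with a library left out.

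Replicates share numbers across adapters, and the labels do not say whether same-numbered libraries share RNA. The deviations of same-numbered libraries did not move together (correlation −0.027 over 39431 sequences). The filter keeps sequences that are abundant with either adapter, and counting noise in those scarce with the other can hide a shared deviation. The correlation therefore cannot decide whether same-numbered libraries share RNA. With a replicate block, 16274 sequences were higher and 11845 lower, 19 and 6 miRNAs, and 3 and 15 classes of first base and length. The block left 21, 23 and 24 nt at −0.43, 0.33 and 0.40 (adjusted p = 0.127 each).

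Mean rho within adapters was 0.966 at 10 CPM or more and 0.737 over sequences with reads in every library, and between adapters −0.125 and 0.404. Mean Pearson r within adapters was 0.968 with a pseudocount of 5 CPM, 0.98 at 10 CPM or more and 0.921 over sequences in every library. Between adapters it was 0.0367 and 0.359 with pseudocounts of 0.5 and 5 CPM, 0.0309 at 10 CPM or more and 0.587 over sequences in every library. The ratios of complexity moved by less than their SD. At this depth, with 2 libraries per adapter and a simulated dispersion of 0.02, the self-test recovered 20% of sequences changed 2-fold. Differences of that size or smaller can therefore be missed when few sequences differ. Most tested sequences were called in the data, so the rate there is not known. Depth and number of libraries were not varied.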

Other observations

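The ratios of strands, the nested set of reads and the counts of end motifs were chosen after the values were seen. The more abundant strand of the miR166 duplex changed with the adapter. With HD adapters the miR166 passenger strand had 7.51 ± 0.69 reads per guide read and with standard adapters 0.50 ± 0.15 (SD, n = 2). The exact mature and passenger sequences were counted. For miR390, the trigger of the trans-acting siRNA pathway that needs RDR6, the ratio was 1.64 ± 0.28 with HD adapters and 0.027 ± 0.0042 with standard adapters. The latter rested on 1 and 2 passenger reads, and its SD does not cover their counting error. For miR396a the ratio was 0.0083 ± 0.0002 and 0.0017 ± 0.0001, and for miR168 0.49 ± 0.11 and 0.36 ± 0.058. Summed over end variants, the ratio was 3.65 ± 0.056 and 0.19 ± 0.046 for miR166, and 0.91 ± 0.070 and 0.50 ± 0.082 for miR390, whose guide strand was then the more abundant with both adapters. The summed ratio was 0.0073 ± 0.0004 and 0.0026 ± 0.0004 for miR396a with miR396b, and 0.43 ± 0.098 and 0.20 ± 0.0053 for the listed miR168 forms. The summed miR166 guide had 851 ± 69.7 CPM with HD adapters and 21127 ± 1100 CPM with standard adapters (log2 fold change −4.38, limma adjusted p = 4.37e-06).

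A nested set of reads that share the 3′ end GACCGGTAGACTTGAAC made up 1.08% ± 0.042 of reads with HD adapters and 4.97% ± 0.49 with standard adapters. Its 23-nt form CTAACAGACCGGTAGACTTGAAC had 2680 ± 131 CPM and 8851 ± 57.5 CPM, a 3.30-fold difference in means, and its 18-nt form AGACCGGTAGACTTGAAC 1235 ± 125 CPM and 9045 ± 2613 CPM, 7.33-fold. Reads with 12 bases of the 5′ adapter made up 0.959% and 1.64% of reads in the HD libraries and 0.0571% and 0.0618% in the standard libraries.

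Among the tested listed miRNAs, 4 hold ATTCC or TTCCA in their last 8 bases. Of these miR482a (log2 fold change 4.83), miR5300 (2.36) and miR482c (0.73) were higher with HD adapters and miR166 (−4.20) was lower, as was its form TCTCGGACCAGGCTTCATTCC (−6.34), which ends in the motif. Across the 891 tested sequences with that motif, none of which holds 12 bases of the 5′ adapter, the median log2 fold change was 5.32, against 0.19 for those with neither the motif nor adapter bases.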
